A study of Mus musculus with 10 samples.

How the data were processed

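Expression was measured by RNA sequencing in tumors of the mouse melanoma line B16F10 that carried an Ly86 overexpression construct or a vector control. Per the labels, RNA was extracted with TRIzol, libraries were made from polyadenylated RNA, and sequencing was done on a NovaSeq instrument. The submitters' processing notes name STAR 2.7.10b, a spliced aligner, RSEM 1.3.3, which estimates transcript abundance, and the mouse genome build mm39. The deposited table holds log2(TPM + 1) values, where TPM is transcripts per 1000000 of the library, for 27919 gene symbols in 10 libraries. That scale is not stated in the sources used here and was read from the values. Raising 2 to a value and subtracting 1 gave a multiple of 0.01, to within 1e-04 hundredths, for 99.9% of values, and the results summed to between 994679 and 996446 per library. How the authors handled symbols that occur more than once is not given in the sources used here. TPM keeps no record of read depth, so the depth of each library is unknown and no counting interval is given. The table names genes by symbol only, and no coordinates are printed, since an annotation of mm39 was not used here. Near-identical genes such as Cd209f and Cd209g, Lyz1 and Lyz2, H2-Q6 and H2-Q7, or members of the Gbp and Ifit families can share reads, so their separate values are uncertain.

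The labels mark 2 libraries each from Ly86 tumor 1, vector tumor 1 and vector tumor 2 as parts of the same tumor, called pieces here. The tumor was the replicate. The log2 values of the pieces were averaged, which left 4 Ly86 and 3 vector tumors. The labels number the tumors without saying that each came from a different mouse, so p-values measure the spread between these tumors, part of which can be technical. Genes with a mean TPM of at least 1 over the tumors were tested, 14556 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(TPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Ly86 minus vector on this scale and understate the change of genes with low values. The planned test had assumed TPM, and the log2(TPM + 1) values needed no other test.

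A set of 34 gene lists with 659 genes was fixed before the data were examined, as were the tests and the rule for naming genes. Of these genes, 10 were absent from the table. Lists with at least 5 tested members entered limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry. A list score was the mean log2(TPM + 1) of its tested members, compared between groups by a two-sided exact permutation test over all 35 assignments of the 7 tumors, for which the smallest p is 0.0286. After adjustment over the 34 lists, a score could pass only if most of the lists reached that smallest p. Many lists overlap in biology, and some genes are on more than 1 list. The rule for naming genes took Ly86 first and then the genes past the threshold. Where fewer than 5 passed in a direction, the genes with the smallest unadjusted p brought the number to 5, leaving out predicted genes with Gm or Rik names. It added Cd180, Tlr4, Ly96 and the 2 to 4 members with the smallest unadjusted p of each list past the threshold.

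The fits were tested on simulated data. In a simulation of the Ly86 and vector tumors over 14556 genes, 200 of them changed, limma recovered 53.7% of the genes changed by 1 log2 unit, 83.6% of those changed by 2 and 100% of those changed by 4, with 5 false calls. It drew genes independently and with the same SD in both groups. The real genes were correlated, and the macrophage list score had an SD of 0.13 in Ly86 tumors and 0.90 in vector tumors. These rates therefore do not give the power of the real comparison. In 50 simulated data sets that kept the tumors' own correlation between genes and had no group effect, camera at the preset correlation called a median of 15.5 of the 34 lists and at most 30. With independent unchanged genes it called 0.

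The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a minimum mean TPM of 5, median-of-ratios scaling, quantile normalization, and leaving out mitochondrially encoded and hemoglobin genes. Other alternatives were a fit of 10 libraries with the tumor as a random block, each piece of the divided tumors alone, eBayes without trend and with robust estimation, limma's array weights, the tumor number as a block, and leaving out each tumor in turn. Leaving out the first piece of vector tumor 2 was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.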

Results

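RNA sequencing covered tumors of B16F10, a mouse melanoma line, that either overexpressed Ly86 or carried the vector. All mice had been given 4 rounds of antibodies against PD-1 and CTLA4, which block inhibitory receptors of T cells, and the tumors were snap-frozen at harvest. The data comprised 10 libraries of polyadenylated RNA from 7 tumors, 4 with Ly86 and 3 with vector. Ly86 tumor 1 and vector tumors 1 and 2 were each represented by 2 pieces, which were averaged so that the tumor was the replicate. Between 19304 and 21882 of the 27919 genes in the table had a value above 0 in a library. Values were log2(TPM + 1), and read depth was unknown because TPM does not retain it.

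The first comparison asked whether Ly86 was higher in the tumors made to overexpress it. Ly86 encodes MD-1, a secreted protein that pairs with the receptor RP105 (Cd180) on B cells and myeloid cells. The sources used here do not state whether reads of the introduced Ly86 count toward this gene. Its mRNA averaged 5.98 ± 0.21 log2(TPM + 1) (SD, n = 4) in the Ly86 tumors and 4.29 ± 0.99 (SD, n = 3) in the vector tumors, a log2 difference of 1.69 (SE 0.40). Every Ly86 tumor lay above every vector tumor, with an exact permutation p of 0.0286, the smallest that 35 assignments allow. Across all tested genes the difference did not pass, with a limma adjusted p of 0.437. The 5 libraries of Ly86 tumors held 49.2 to 81.9 TPM of Ly86. In the vector group, the pieces of tumor 1 held 6.24 and 9.88 TPM and tumor 3 held 30.3 TPM. Vector tumor 2 held 80.9 TPM in its first piece and 7.85 TPM in its second, so 1 vector library lay within the Ly86 range. The log2 difference was 1.12 (limma adjusted p = 0.356) without vector tumor 1 and 1.07 (adjusted p = 0.0424) with limma's array weights. Over all alternative settings it ranged from 1.07 to 2.23 and its adjusted p from 0.0424 to 1.

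**Figure D1:**
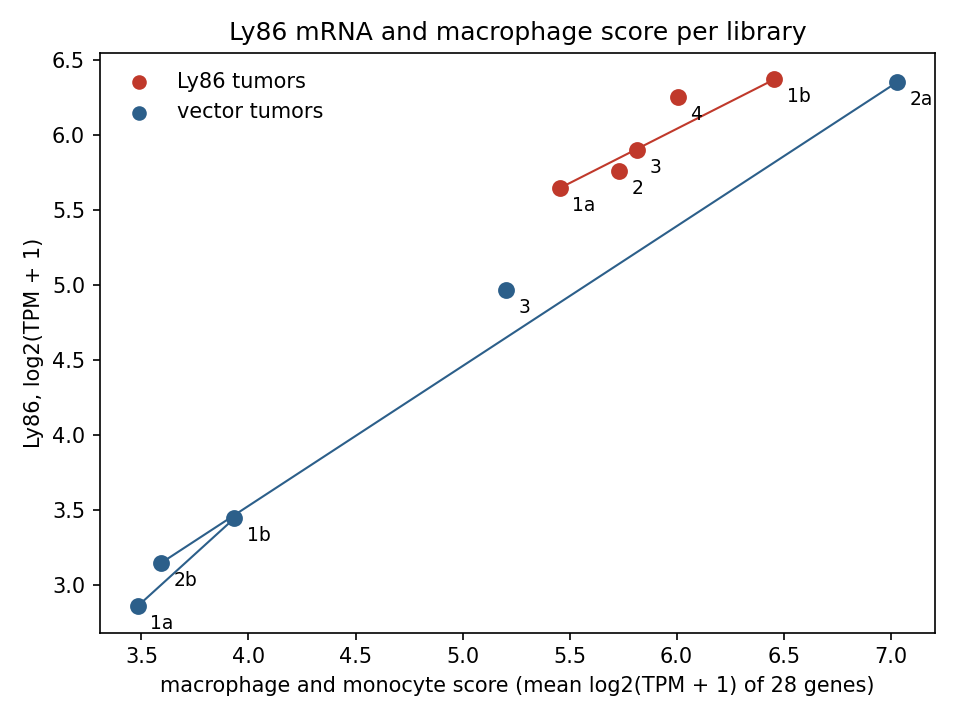
Ly86 mRNA against the macrophage and monocyte score, both in log2(TPM + 1), in the 10 libraries. Labels give the tumor number, a and b are the first and second piece of a divided tumor, and lines join the pieces; all 5 Ly86 libraries have Ly86 minus score of -0.083 to 0.25, above the -0.68 to -0.23 of the 5 vector libraries.

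Cd180, the receptor that MD-1 binds, averaged 1.48 log2 units higher in the Ly86 tumors (SE 0.48, limma adjusted p = 0.437). It was 2.20 log2(TPM + 1) in vector tumor 1, against 3.59 and 3.90 in vector tumors 2 and 3. Ly86 tumor 3, at 3.70, lay below vector tumor 3. Ly96, which encodes MD-2, the partner of the lipopolysaccharide receptor, differed by 0.40 (SE 0.15, adjusted p = 0.449). Tlr4, the receptor itself, differed by 0.10 (SE 0.16, adjusted p = 0.859). In the list of TLR4 and RP105 receptor complex and adaptors, 15 of 18 tested members were higher, with a mean log2 fold change of 0.51. Lbp, which carries lipopolysaccharide to its receptor, differed by 2.11 (SE 0.41) and the adaptor Ticam2 by 0.74 (SE 0.26). In limma, 1 member passed when adjusted over the list alone and 0 over all genes. The list passed camera at the preset correlation, with an adjusted p of 0.375 with an estimated correlation. Its mean was 0.28 without vector tumor 1, 0.29 with only the first piece of each divided tumor and 0.74 with only the second.

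Over the transcriptome no gene passed, and the genes named here are those with the smallest unadjusted p. F13a1, the A chain of coagulation factor XIII, was 1.84 log2 units higher in the Ly86 tumors (SE 0.27). The lectin genes Cd209f and Cd209g were 2.36 (SE 0.36) and 1.96 (SE 0.31) higher, the lysozyme gene Lyz1 2.06 (SE 0.31) and the secreted protease gene Htra3 1.97 (SE 0.32). On the lower side stood Rpph1, the RNA of ribonuclease P, at -3.18 (SE 0.52), Limch1 at -1.16 (SE 0.19) and the metalloprotease gene Adam12 at -0.90 (SE 0.15). Slc7a1, a transporter of cationic amino acids, stood at -0.56 (SE 0.10) and Topbp1, which acts in DNA replication and repair, at -0.48 (SE 0.092). None of these passed, with limma adjusted p of 0.393 for the first 8 and 0.409 for Slc7a1 and Topbp1. In all, 0 of 14556 genes passed. At an unadjusted p under 0.05 there were 1565 genes, 841 higher and 724 lower, where 728 would be reached by chance. The groups did not overlap for 686 higher and 837 lower genes, 10.5% of those tested against 5.71% by chance. The count and its balance depended on single tumors. It was 872 without vector tumor 1 (486 higher, 386 lower), 2587 without vector tumor 2 (1244 and 1343), 999 without vector tumor 3 (749 and 250), 1487 without Ly86 tumor 1 (601 and 886), 1298 without Ly86 tumor 2 (665 and 633), 1414 without Ly86 tumor 3 (859 and 555), 988 without Ly86 tumor 4 (500 and 488) and 3012 without the first piece of vector tumor 2 (1633 and 1379). With only the first piece of each divided tumor it was 318, 126 higher and 192 lower, fewer than by chance, and with only the second it was 3319, 1578 higher and 1741 lower. With array weights 1832 genes passed, 626 higher and 1206 lower, in a fit that gave vector tumor 3 a weight of 22.8 and each other tumor less than 1.

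Myeloid and inflammatory genes averaged higher in the Ly86 tumors, in lists that passed only camera at the preset correlation. Of 28 tested macrophage and monocyte genes, 27 were higher in the Ly86 tumors, with a mean log2 fold change of 1.14, and the list score was 5.88 ± 0.13 (SD, n = 4) against 4.74 ± 0.90 (SD, n = 3). Lyve1 and Folr2, both marks of resident macrophages, differed by 2.09 (SE 0.39) and 1.97 (SE 0.39). Lyz2 differed by 1.36 (SE 0.28) and Spp1, which encodes osteopontin, by 0.76 (SE 0.17). In the complement and coagulation list, 19 of 20 members were higher with a mean of 1.14, among them C3 at 2.55 (SE 0.57), the receptor gene C3ar1 at 1.64 (SE 0.38) and C1s1 at 1.75 (SE 0.49). Of 30 chemokines, 27 were higher with a mean of 0.97. The monocyte attractants Ccl2 and Ccl7 differed by 1.68 (SE 0.38) and 2.03 (SE 0.46), and Ccl3 and Ccl4 by 1.82 (SE 0.41) and 1.71 (SE 0.42). Of 22 NF-kB inflammatory targets, 21 were higher with a mean of 0.86, including Bcl2a1b, a survival gene, at 1.18 (SE 0.33). In the neutrophil list, 9 of 11 members were higher with a mean of 0.64, with Mmp9 at 1.23 (SE 0.31) and Csf3r, the receptor for granulocyte colony-stimulating factor, at 0.80 (SE 0.35). Adjusted over the list alone, limma passed 21 macrophage, 8 complement, 11 chemokine, 6 NF-kB and 1 neutrophil genes, and over all genes 0.

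All 5 of these lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.375 for the macrophage, complement, chemokine and NF-kB lists and 0.400 for neutrophils. The macrophage, complement and NF-kB scores were higher in every Ly86 tumor than in every vector tumor, each with an exact permutation p of 0.0286, which became 0.216 after adjustment over 34 lists. Without vector tumor 1 the means were 0.62 for macrophages, 0.65 for complement, 0.53 for chemokines, 0.50 for NF-kB targets and 0.28 for neutrophils. With only the first piece of each divided tumor they were 0.51 for macrophages, 0.61 for complement, 0.46 for chemokines, 0.49 for NF-kB targets and 0.027 for neutrophils, and with only the second 1.76, 1.66, 1.49, 1.23 and 1.25. Without the first piece of vector tumor 2 the macrophage mean was 1.71. The neutrophil mean was 0.40 without Ly86 tumor 3, 0.97 without vector tumor 2 and 1.19 without the first piece of vector tumor 2.

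Genes of interferon responses and antigen presentation also averaged higher, in lists that passed only that test. All 31 tested members of the type I interferon list were higher, with a mean log2 fold change of 0.95, among them Ifi27l2a at 1.55 (SE 0.49), Ifit1 at 1.01 (SE 0.33) and Irf9, a subunit of the interferon-activated factor ISGF3, at 0.64 (SE 0.23). All 27 interferon gamma response genes were higher with a mean of 1.31, including Socs1, a feedback inhibitor of cytokine signaling, at 1.54 (SE 0.39) and the GTPase genes Gbp2b at 1.89 (SE 0.72) and Irgm2 at 1.56 (SE 0.62). In the MHC class I list 19 of 20 members were higher with a mean of 0.94. B2m, the shared light chain, differed by 1.04 (SE 0.35), H2-K1 by 1.29 (SE 0.53) and H2-Q6 by 1.67 (SE 0.56). All 12 MHC class II genes were higher with a mean of 1.10, with Ctss, the protease that trims the invariant chain, at 1.50 (SE 0.43) and Cd74, the invariant chain, at 1.62 (SE 0.83). No gene of these 4 lists passed limma, either adjusted over the list alone or over all genes. The lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.375 for both interferon lists and MHC class I and 0.383 for MHC class II. The spread in the vector group was wide, with an interferon gamma score of 6.84 ± 0.61 (SD, n = 4) in Ly86 tumors and 5.53 ± 1.60 (SD, n = 3) in vector tumors. Without vector tumor 1 the means were 0.37 for type I interferon, 0.38 for interferon gamma, 0.28 for MHC class I and 0.31 for MHC class II. With only the first piece of each divided tumor they were 0.65, 0.99, 0.67 and 0.76, in the same order, and with only the second 1.25, 1.62, 1.21 and 1.45.

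Genes of the lymphocyte, co-stimulation and dendritic cell lists averaged higher as well, with wide errors and in lists that passed only camera at the preset correlation. Genes on these lists need not come from lymphocytes alone. All 20 genes of the CD8 T and cytotoxic list were higher, with a mean log2 fold change of 1.30. Prf1, which encodes perforin, differed by 1.81 (SE 0.56), Ccl5 by 1.50 (SE 0.50) and the granzyme gene Gzmd by 1.74 (SE 0.60). In the T cell list 20 of 21 genes were higher with a mean of 0.73, with Cd3g at 1.61 (SE 0.61) and Cd2 at 1.17 (SE 0.47). All 6 NK cell genes were higher with a mean of 0.87, with Xcl1 at 0.89 (SE 0.35) and the receptor gene Klrc1 at 1.38 (SE 0.57). Of 18 checkpoint and exhaustion genes 16 were higher with a mean of 0.65. Vsir, which encodes the inhibitory receptor VISTA, differed by 1.34 (SE 0.36), and Nr4a1 was on the lower side at -0.25 (SE 0.11). All 7 regulatory T cell genes were higher with a mean of 0.51, with Tnfrsf9 at 1.27 (SE 0.36) and Il10 at 0.74 (SE 0.41). Of 13 co-stimulation genes 12 were higher with a mean of 0.66, including the adhesion receptor gene Cd226 at 1.45 (SE 0.31) and Cd40 at 1.31 (SE 0.38). In the dendritic cell list 14 of 16 genes were higher with a mean of 0.54, with Tlr3 at 0.62 (SE 0.19) and Clec9a at 0.86 (SE 0.32). All 6 B and plasma cell genes were higher with a mean of 1.08. The antibody genes Ighm and Igkc differed by 2.47 (SE 0.54) and 2.11 (SE 0.97). In the lymph node and tertiary lymphoid list 5 of 7 genes were higher with a mean of 0.37, among them the B cell attractant Cxcl13 at 1.33 (SE 0.53) and Ltb at 0.90 (SE 0.37).

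In limma, adjusted over the list alone, 3 co-stimulation genes and 1 B and plasma cell gene passed, with 0 in the other 7 lymphocyte and dendritic cell lists and 0 over all genes. All 9 lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.375 for the CD8, NK, co-stimulation, dendritic and B cell lists, 0.400 for the T cell, checkpoint and regulatory T cell lists, and 0.446 for the lymph node list. Without vector tumor 1 the means were 0.75 for CD8 T cells, 0.27 for T cells, 0.49 for NK cells, 0.26 for checkpoints, 0.19 for regulatory T cells, 0.38 for co-stimulation, 0.26 for dendritic cells and -0.068 for the lymph node list. With only the first piece of each divided tumor they were 0.95, 0.40, 0.42, 0.37, 0.21, 0.38, 0.27 and -0.15, in the same order, with 0.72 for B cells. With only the second piece the 9 means ranged from 0.81 for dendritic cells to 1.64 for CD8 T cells. The regulatory T cell mean was 0.87 without vector tumor 2 and 0.82 without its first piece. The lymph node mean was 0.17 without Ly86 tumor 1, 0.76 without vector tumor 2 and 0.88 without its first piece, and the B cell mean was 0.70 without Ly86 tumor 3.

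**Figure D2:**
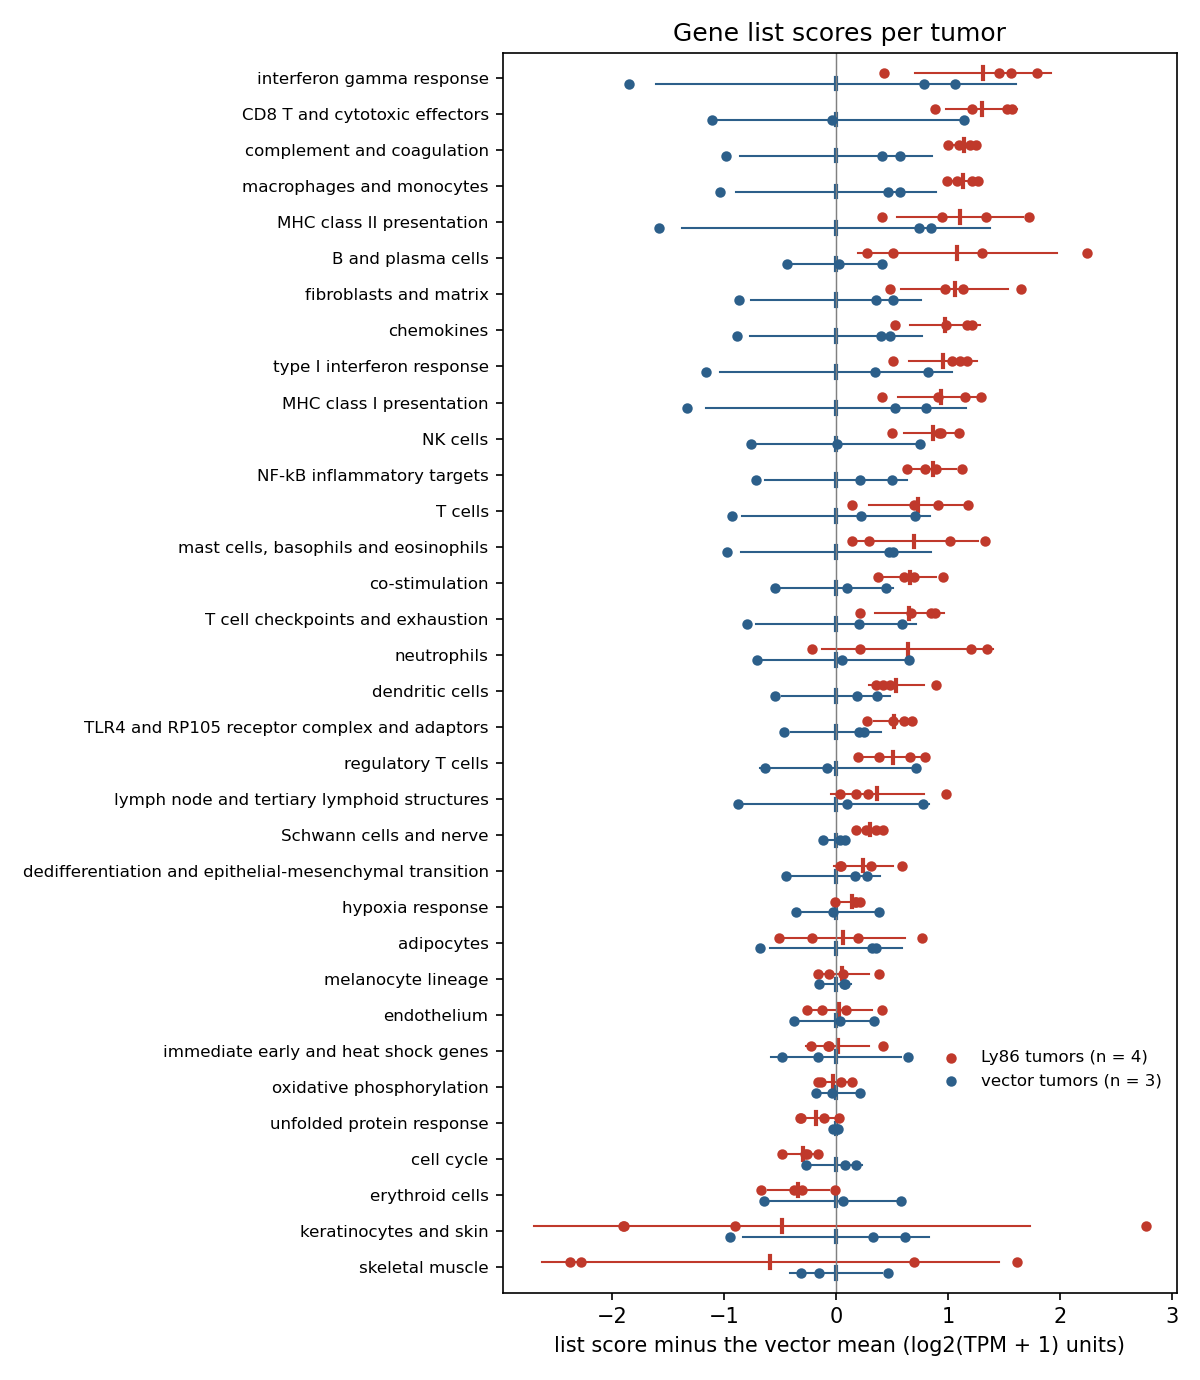
Scores of the 34 gene lists per tumor, in log2(TPM + 1) units, with the mean of the vector tumors set to 0. Points are tumors, upright bars are group means and lines span 1 SD; the macrophage, complement, NF-kB, chemokine, TLR4 and Schwann lists are the 6 in which no vector tumor reaches a Ly86 tumor.

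Matrix genes averaged higher and cell cycle genes lower in the Ly86 tumors, in lists that passed only camera at the preset correlation. Of 25 fibroblast and matrix genes 23 were higher, with a mean log2 fold change of 1.06. The proteoglycan genes Dcn and Lum differed by 2.39 (SE 0.45) and 1.50 (SE 0.32), and Dpt and Pi16, which mark fibroblasts of dermis and vessel sheaths, by 2.30 (SE 0.44) and 2.54 (SE 0.58). All 28 cell cycle genes were on the lower side with a mean of -0.29, including the replication helicase genes Mcm2 at -0.51 (SE 0.12) and Mcm5 at -0.43 (SE 0.12) and the mitotic kinase gene Aurkb at -0.42 (SE 0.12). Of 20 unfolded protein response genes 17 were lower and 3 higher with a mean of -0.18, with Manf at -0.38 (SE 0.13) and the chaperone gene Hyou1 at -0.54 (SE 0.20). Of 24 dedifferentiation and epithelial-mesenchymal genes 16 were higher with a mean of 0.24, among them Ngfr at 0.96 (SE 0.30) and Twist1 at 0.70 (SE 0.27). Of 25 hypoxia genes 20 were higher with a mean of 0.14, with P4ha1 at 0.32 (SE 0.12) and Car9 at 0.57 (SE 0.25). Adjusted over the list alone, limma passed 9 fibroblast genes and 0 in the other 4 lists, and 0 over all genes.

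These 5 lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.375 for the fibroblast, cell cycle and unfolded protein response lists, 0.513 for dedifferentiation and 0.613 for hypoxia. Without vector tumor 1 the mean was 0.62 for fibroblasts, 0.022 for dedifferentiation and -0.039 for hypoxia. With only the first piece of each divided tumor it was 0.48 for fibroblasts, -0.17 for cell cycle, -0.098 for the unfolded protein response, -0.023 for dedifferentiation and 0.044 for hypoxia, and with only the second 1.63, -0.42, -0.26, 0.51 and 0.23. Without the first piece of vector tumor 2 it was 1.78 for fibroblasts and 0.49 for dedifferentiation, which was 0.13 without Ly86 tumor 1 and 0.38 without vector tumor 2. The hypoxia mean was 0.33 without vector tumor 2.

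Melanocyte lineage genes did not separate the groups. Their score was 8.01 ± 0.24 (SD, n = 4) in Ly86 tumors and 7.96 ± 0.13 (SD, n = 3) in vector tumors, and the mean log2 fold change of 22 genes was 0.053. The other lists that did not pass camera had means of 0.031 for endothelium, with a median of -0.049, 0.31 for Schwann cells and nerve, 0.70 for mast cells, basophils and eosinophils, and 0.061 for adipocytes. Means were -0.58 for skeletal muscle, -0.48 for keratinocytes, -0.34 for erythroid cells, -0.026 for oxidative phosphorylation, and 0.014 for immediate early and heat shock genes, with a median of -0.081. Several of these means depended on 1 tumor or piece. The keratinocyte mean was -1.56 without Ly86 tumor 1 and 0.37 without the first piece of vector tumor 2, and the muscle mean -1.32 without Ly86 tumor 2 and 0.010 without Ly86 tumor 3. The erythroid mean was -0.66 without vector tumor 3 and -0.047 without vector tumor 1, and the mast cell mean 0.21 without vector tumor 1 and 1.38 without the first piece of vector tumor 2. The adipocyte mean was -0.28 without vector tumor 1 and 0.73 without the first piece of vector tumor 2, and the endothelium mean -0.16 and 0.39 in the same settings. Without vector tumor 1 and without vector tumor 2, the mean was -0.23 and 0.34 for immediate early and heat shock genes and 0.081 and -0.11 for oxidative phosphorylation. With only the first piece of each divided tumor and with only the second, the mean was -0.51 and 0.63 for adipocytes, -0.26 and 0.32 for endothelium, 0.16 and 1.24 for mast cells, -1.23 and 0.059 for muscle, -0.61 and -0.066 for erythroid cells, -0.65 and -0.31 for keratinocytes, -0.078 and 0.11 for immediate early genes, and 0.17 and -0.063 for melanocyte genes. Muscle and skin genes varied most between Ly86 tumors, with a keratinocyte score of 1.97 ± 2.21 (SD, n = 4) against 2.45 ± 0.83 (SD, n = 3). The Schwann cell score was higher in every Ly86 tumor, at 4.55 ± 0.10 (SD, n = 4) against 4.25 ± 0.10 (SD, n = 3), with an exact permutation p of 0.0286 that became 0.216 after adjustment over 34 lists.

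Over all 34 lists, camera at the preset correlation passed 22 as higher and 2 as lower. With an estimated correlation 0 passed (smallest adjusted p = 0.375), and 0 passed fry, either for movement in one direction (smallest adjusted p = 0.294) or in either direction (0.195). The exact permutation test of list scores gave 4 lists at an unadjusted p under 0.05 and 0 after adjustment. That 0 says little, since a list that separated the groups fully could pass only if most of the 34 lists did so too. Scores did not overlap between the groups in 6 of the 34 lists, where chance would give 5.71%.

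The last comparison set the pieces of a divided tumor beside different tumors. The first piece of vector tumor 2 was richer than the second in macrophage, fibroblast, skin and fat genes, with list scores higher by 3.44, 4.34, 5.13 and 4.02 log2 units, and its melanocyte score was lower, at -0.62. Krt14, a keratin of basal skin cells, was at 139 TPM in the first piece and listed at 0 in the second. In Ly86 tumor 1, the first piece had a keratinocyte score higher by 4.11 than the second and a muscle score lower, at -4.41. In vector tumor 1 the first minus second differences were -2.30 for muscle, -1.20 for fibroblasts and -0.45 for macrophages. Over genes, the SD of the log2 difference between pieces of a tumor was 0.584 in vector tumor 1, 0.660 in Ly86 tumor 1 and 1.10 in vector tumor 2, with a mean of 0.780, or 0.622 without vector tumor 2. Between libraries from different tumors of one group it averaged 0.764 (17 pairs), and between groups 0.816 (25 pairs). The first principal component held 42.8% of the variance, with the first piece of vector tumor 2 at -68.9 on one end and the first piece of vector tumor 1 at 71.3 on the other.

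**Figure D3:**
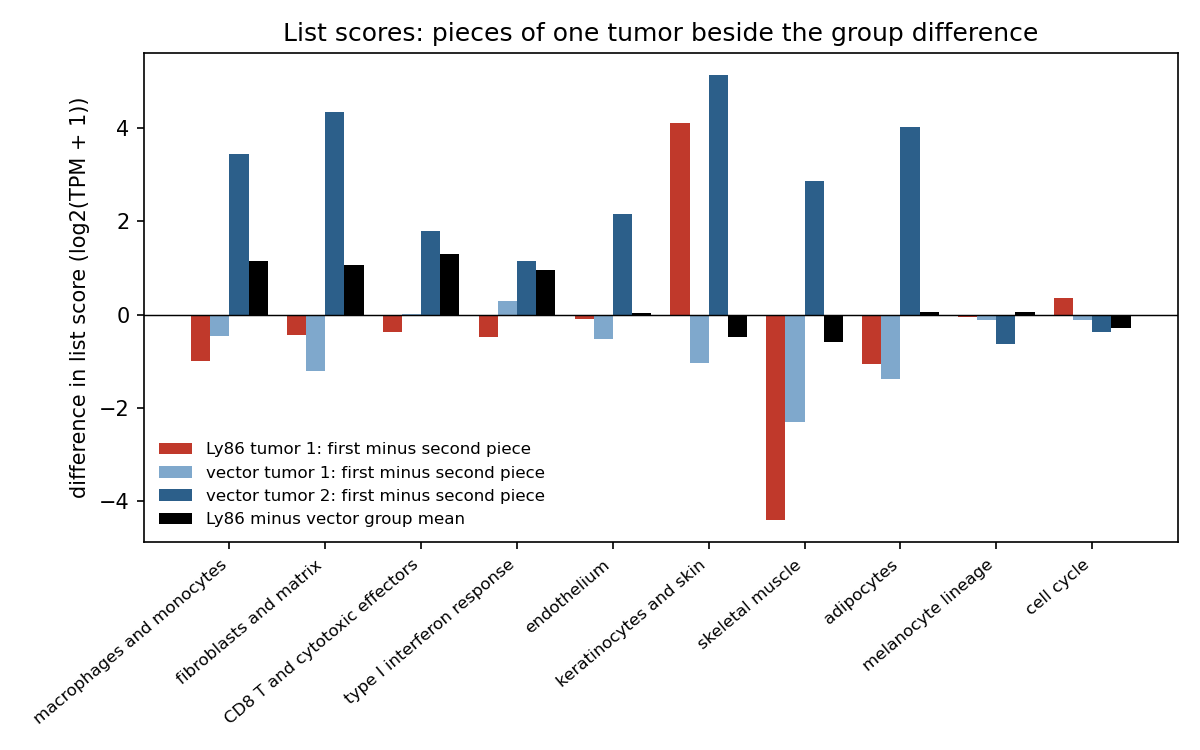
Differences in list score, in log2(TPM + 1) units, between the first and second piece of the 3 divided tumors, beside the difference between group means of the 4 Ly86 and 3 vector tumors in black. For the macrophage list the pieces of vector tumor 2 differ by 3.44 and the groups by 1.14.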

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

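The tests of Ly86 against the macrophage score, of the macrophage list and of the fibroblast list were chosen after the results were seen, as were their repeats with a tumor or piece left out. The test of uneven sampling as first written used the average over divided tumors alone, which met the bound for uneven sampling, and the condition that it also hold with each divided tumor left out was added after that value was seen. The test of skin, muscle or fat in Ly86 tumors 3 and 4 was divided after its mean score had argued against all of them together.

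Ly86 mRNA was 1.69 log2 units higher in the Ly86 tumors. Genes of macrophages, cells that make Ly86 themselves, also averaged higher there, in a list that passed only camera at the preset correlation. Over the 7 tumors, Ly86 correlated with the macrophage score at Pearson r = 0.984 (permutation p = 0.000992). A group difference in both can raise that value. Ly86 minus the macrophage score was 0.556 higher in the Ly86 tumors (SE 0.120, exact permutation p = 0.0286). However, 4 of 28 macrophage genes, Lyve1, Folr2, Nos2 and Arg1, had as large an excess, none with an exact p under 0.05. For Lyve1 and Folr2 it was larger, at 0.984 and 0.861, each with an exact permutation p of 0.0571. More myeloid cells as the whole cause therefore cannot be excluded, since macrophage genes that were not introduced parted from the score as far. The introduced Ly86 as most of the log2 difference cannot be told apart from a smaller share, since the group term left after the macrophage score was 0.435 (SE 0.168), more than its SE below the bound of 0.846, but 0.658 (SE 0.151) with only the first piece of each divided tumor, above its bound of 0.583. If reads of the introduced gene count toward Ly86, which the sources used here do not state, that remaining part is consistent with its expression (permutation p = 0.0149), but it was 0.170 (SE 0.129) without vector tumor 2 and 6 of 28 macrophage genes had as large a group term, so a change in the kind of myeloid cell stays open. The bounds first written for the introduced gene could both be met, so this test was divided into a test of most of the difference and a test of the rest, and the condition that the former hold with a tumor or piece left out was added after the 0.435 was seen.

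The macrophage and monocyte list was 1.14 log2 units higher in the Ly86 tumors. If a lower share of melanoma cells raised endothelium alike, macrophage minus endothelium would not differ between the groups. It was 1.11 higher in the Ly86 tumors (SE 0.345, exact permutation p = 0.0286). With only the first piece of each divided tumor it was 0.769 higher (SE 0.466, exact permutation p = 0.114). This value also shifted between pieces of a tumor, by 1.28 in vector tumor 2, -0.90 in Ly86 tumor 1 and 0.063 in vector tumor 1. That spread alone would give the group difference an SE of 0.425, still below the 1.11. In vector tumor 2, first minus second piece was -0.62 for melanocyte genes, 3.44 for macrophages and 2.15 for endothelium. The 2 lists did not rise alike there, so the test cannot decide on a lower share of melanoma cells. Uneven sampling of tumor regions cannot be told apart from a difference between the groups, since the score differed between pieces of a tumor by 1.63 on average (SD 1.59, 3 tumors) but by 0.727 without vector tumor 2. An effect of Ly86 on the cells that enter the tumor was not tested and stays open.

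The fibroblast and matrix list was 1.06 log2 units higher in the Ly86 tumors. Skin, muscle or fat taken along with the tumor cannot be told apart from a difference in tumor stroma over all 7 tumors, since the fibroblast score minus the mean of the keratinocyte, muscle and adipocyte scores differed by 1.39 with a wide error (SE 0.901, exact permutation p = 0.371). Ly86 tumors 3 and 4 were singled out after their scores were seen. Their fibroblast scores of 5.72 and 6.23 lay above the highest vector score of 5.10, that of vector tumor 2. That score averaged 7.27 in its first piece and 2.93 in its second. Ly86 tumor 1, at 5.56, also lay above 5.10. In Ly86 tumors 3 and 4 the fibroblast score minus the mean of the keratinocyte and muscle scores lay at least 2.98 above every vector tumor (SD of the vector tumors 0.265). Skin with keratinocytes, or muscle, was thus scarce in them by these scores. Since they were chosen by scores already seen, this cannot decide on skin or muscle as a cause of the group difference. Skin without keratinocytes was not tested. Part of that gap came from the keratinocyte and muscle means of 0.57 and 0.62, which were the lowest of all tumors. Fat in those tumors cannot be told apart from a difference in stroma by the same bounds, since their adipocyte scores of 2.34 and 2.64 lay above the 2.17 of vector tumor 1, although the fibroblast minus adipocyte score lay at least 1.49 above every vector tumor (SD 0.177). Connective tissue without skin, muscle or fat and an effect of Ly86 on fibroblasts were not tested and stay open.

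Of 137 sets of 4 Ly86 tumors, for named genes and list scores, 4 had a tumor far from the others, where chance gives about 1 in 20. Slc7a1 was 5.58 log2(TPM + 1) in Ly86 tumor 1 against 5.35 to 5.36 in the others. Itgax was 3.56 in Ly86 tumor 1 against 2.97 to 3.01. Xcl1 was 1.26 in Ly86 tumor 3 against 2.41 to 2.51. Cd79b was 1.93 in Ly86 tumor 4 against 1.32 to 1.37.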

How the results depend on the processing

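Leaving out the first piece of vector tumor 2 was chosen after the data were seen; all other settings were planned. The count of 0 genes in limma became 1 with the first piece only of each divided tumor (Gm50083, lower), 6 with the second only (Clec3b, Igfbp6, Ltc4s and Spp1 higher, Fads2 and Gm17119 lower), 1832 with array weights, and 1 without the first piece of vector tumor 2 (Gm17119). Leaving out each tumor gave 0 to 2 genes: Gm55882 and Rpph1 without Ly86 tumor 2, Gm49739 without Ly86 tumor 3, Gm50083 without vector tumor 1 and Gm17119 without vector tumor 2. These genes were named after their values were seen. The Ly86 fold change passed under array weights alone (1.07), among 22 settings. The 24 lists became 0 with an estimated correlation and 0 with fry, and 18 to 27 in the other settings; 17 of the 24 passed in each of those. With each tumor left out, the mean fold change of the hypoxia list ranged from -0.0387 (without vector tumor 1, camera adjusted p = 0.739) to 0.331 and that of the oxidative phosphorylation list from -0.114 to 0.0814 (without vector tumor 1, adjusted p = 0.0212). Without the first piece of vector tumor 2, 14 list scores had an unadjusted exact p under 0.05 and 0 passed after adjustment (smallest 0.0694). List scores with a tumor left out could not pass, since their smallest exact p is 0.1 or 0.0667. The spread between pieces rose to 1.15 with a pseudocount of 0.1, which widens differences of low genes. Of 2220 values of 102 named genes, 58 came to pass, 56 of them under array weights. The sign changed in 5 values, none of which passed, and 0 values passed with the opposite sign. No scaling moved the median of all genes by over 0.1 or turned the mean of a list that passed. With the tumor number as a block, 0 genes and 23 lists passed, Ly86 differed by 1.60 and 645 genes had an unadjusted p under 0.05. Whether tumors of the same number belong together is not stated in the sources used here. Deviations of tumors with the same number correlated at -0.17, -0.11 and -0.31. Of 3 vector tumors, 0 correlated best with the Ly86 tumor of its own number. These values give no sign of pairing but cannot exclude it, since the spread within a tumor could be large. The SD between pieces averaged 0.780, or 0.622 without vector tumor 2, against 0.764 between different tumors of one group. Causes other than those given were not tested.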

Other observations

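Some macrophage genes were looked up singly after their values were seen, and none passed. Cd5l, which encodes a secreted protein of resident macrophages, differed by 2.10 log2 units (SE 0.41, limma adjusted p = 0.409), Cbr2 by 1.72 (SE 0.32, adjusted p = 0.409), Clec10a by 1.82 (SE 0.42, adjusted p = 0.437) and Cd163 by 1.29 (SE 0.39, adjusted p = 0.437). Ccl8, a chemokine gene, differed by 1.98 (SE 0.62) and Retnla, which is induced by interleukin 4, by 4.26 (SE 1.21), each with an adjusted p of 0.437. Chil3, another gene induced by interleukin 4, differed by -0.085 (SE 0.60, adjusted p = 0.976). Cd209a, a lectin gene of dendritic cells, differed by 0.50 (SE 0.32, adjusted p = 0.601), less than its relatives Cd209f and Cd209g.

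Of other genes looked up singly after their values were seen, Clec3b differed by 3.14 (SE 0.64), Efemp1 by 2.25 (SE 0.46) and Tnxb by 1.64 (SE 0.33), each with a limma adjusted p of 0.437. The melanocyte genes Pmel and Tyr stood at 0.010 (SE 0.22, adjusted p = 0.992) and -0.034 (SE 0.18, adjusted p = 0.967).

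RNAs that mostly lack a poly(A) tail were looked up after Rpph1 was seen. Rpph1 differed by -3.18, Rn7s1 and Rn7s2, whose values were identical, by -1.35, Rmrp by -1.30, Terc by -0.15 and Rn7sk by 1.51, none with a limma adjusted p under 0.05.

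Of the tests of other splits of the tumors, the one on genes past the threshold was chosen after the result was seen. For the 0 genes past the threshold, all 35 splits of the 7 tumors gave as many, with 3 genes in the highest other split, which says nothing because no split can give fewer than 0. Chance was not excluded for the other 2 counts. For the 1565 genes at an unadjusted p under 0.05, 2 of the 35 splits gave as many, with 1824 in the highest other split, which put vector tumor 2 with Ly86 tumors 1, 2 and 4. For the 24 lists past camera at the preset correlation, 13 of the 35 splits gave as many, with 30 in the highest other split.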
